A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

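Total RNA from 8 yeast cultures was measured on Affymetrix Yeast 2.0 arrays, 1 array per culture, 4 from the CDC34tm strain and 4 from the wild type (WT). Per the labels' protocols, RNA was extracted with hot acid phenol, and biotin-labelled cRNA was made in a single cycle from cDNA primed with a T7 promoter and oligo-dT. The deposited values are array intensities on a linear scale, as MAS5 signals per the submitters' processing notes. The MAS5 version, the scaling target and any further step are not given in the sources used here. From the values, each array had been scaled to a common level: the mean without the top and bottom 2% of probe sets was 1000 on every array. That scaling was kept, so a change in total mRNA per cell would not be seen.

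The table held 10928 probe sets. Of these, 213 were controls, 5498 were named as 1 S. cerevisiae gene, 1746 as 1 S. pombe gene, 1 was assigned to several genes, and 3470 carried no name in the platform table used. All gene names came from that table, with 12 symbols updated through the gene ID in the RefSeq gene table of the R64 assembly. The RefSeq table was also used for coding length and for the order of neighbouring genes. Coding length here means the length it gives for a gene. That length was a multiple of 3 for 96.8% of genes, so for some others it holds more than coding sequence. No coordinates are given, since the build behind the array design is not given in the sources used here. The array also carries S. pombe probe sets, for which these samples hold no RNA. The 95th percentile of their signals on each array served as background and lay between 12.3 and 14.6. A probe set was tested when it exceeded the background of the same array on at least 4 of the 8 arrays. This kept 5437 S. cerevisiae probe sets for 5392 genes and left out 61 as dim.

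Signals were tested as log2(signal + 16) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend in the mean), CDC34tm against WT, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. A fold change is therefore on the log2(signal + 16) scale, which understates the change of dim genes. Errors are the standard error (SE) of the fit or the standard deviation (SD) over the 4 arrays of a strain. The labels state that the cultures of a strain were separate, so the p-values measure the spread between cultures. The number of arrays, 4 per strain, limits the precision. On simulated data with 200 changed genes among 5437, the same steps recovered 27 of 50 genes changed by 1.25-fold, 44 of 50 changed by 1.5-fold, 48 of 50 changed by 2-fold and 50 of 50 changed by 4-fold, with 5 false calls and 0 calls of the wrong sign. With no gene changed, they made 0 calls. The simulated genes varied independently and with the same spread in both strains. In the real arrays the median SD of log2 signals was 0.131 in WT and 0.0885 in CDC34tm. These counts of false calls may therefore not hold for the real arrays.

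Before the data were examined, 27 gene lists were fixed from general knowledge of yeast. They cover the SCF ubiquitin ligases and their substrates, cell cycle clusters, mating genes, the cell wall, nutrient regulons, stress, ribosomes, the proteasome, DNA damage, respiration, sterols and glycolysis. One further list holds the neighbours of CDC34. The 26 lists with at least 4 measured members were tested with camera at its preset correlation between genes of 0.01, again with an estimated correlation, and with fry, which asks whether the genes of a list move one way on balance. A gene with several probe sets was represented by the brightest. In simulation, 4 of 100 random lists without change reached an unadjusted p under 0.05 and 20 of 20 lists shifted by 0.3 on the log2 scale were called. The simulated genes varied independently of each other, whereas the estimated correlation in the real proteasome list was 0.774. The simulation therefore does not show how the test behaves for lists whose genes vary together. After the data had been seen, 3 lists were added: heat shock genes, the tricarboxylic acid cycle and mitochondrial ribosomal proteins.

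The genes named in the text were set by a rule fixed before the data were examined. It takes CDC34, PST1 and LEU2, the 12 largest rises and the 12 largest falls among called genes without overlap between the strains, and up to 4 members of each called list with the smallest adjusted p. It also takes called members of both SCF lists, and SIC1, CLN1, CLN2 and CTS1. Of the genes and lists fixed in advance, 1 gene and 1 list are not reported here, though the list is among the 26 in counts of lists. Other list members named as examples were chosen after their values were seen.

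Alternatives planned in advance were pseudocounts of 1 and 64, quantile normalization, centring each array on its median, no filter and a stricter filter on dim probe sets, eBayes without the trend, the replicate number as a block, and leaving out each array in turn. Alternatives added after seeing the data were leaving out WT replicates 1 and 4 together, leaving out WT replicates 2 and 3 together, a correction for coding length, and adding the unnamed probe sets. Both pairs of WT arrays were chosen from the values, which can narrow the spread within WT. The p-values without either pair can therefore be too small. Measures of array quality were compared between strains by an exact two-sided permutation test, whose smallest possible p with 4 against 4 arrays is 0.0286. Figures were drawn with matplotlib 3.10.9.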

Results

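Gene expression was measured in a budding yeast strain that carries the CDC34tm allele and in an isogenic wild type. Cdc34 is the ubiquitin-conjugating enzyme that works with SCF ubiquitin ligases, which mark cell cycle regulators and other proteins for the proteasome. Both strains were grown at 30 °C in synthetic medium with 2% dextrose, 0.25% glutamine as nitrogen source and 25.2 mg/L leucine, for 3 to 4 doublings from stationary phase. There were 4 separate cultures per strain and 1 array per culture. The labels name further differences tied to the strain construction: a nourseothricin resistance gene, a partly disrupted 3' region of PST1, and a leu2 allele. The design text lists that allele for the WT strain alone. The source name of every sample, of either strain, names it among the experimental variables, without saying which strain carries it. The median signal of the S. cerevisiae probe sets lay between 1162 and 1244 on the 8 arrays, against a background of 12.3 to 14.6. No pair of arrays held identical values, and correlations of log2 signals were 0.993 to 0.997 within CDC34tm, 0.981 to 0.995 within WT and 0.958 to 0.977 between the strains.

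The comparison of the strains asks what the CDC34tm strain changes in the transcriptome of growing cells. By camera with its preset correlation, G1/S genes and nuclear genes for mitochondrial respiration were higher in CDC34tm as lists, and iron uptake and leucine synthesis genes lower. Heat shock genes were lower as well, in a list that was added after the data were seen. All of these list calls were lost when the correlation was estimated from the arrays. The mRNA of CDC34 itself did not differ, with a mean signal of 1398 ± 57.4 in CDC34tm and 1387 ± 128 in WT (SD, n = 4 each, log2 fold change 0.01, 95% interval -0.16 to 0.19, limma adjusted p = 0.899). PST1, which encodes a cell wall protein and lies next to CDC34, fell 2.14-fold, from 1702 ± 212 to 786 ± 83.0 (SD, n = 4 each, limma adjusted p = 7.34e-05). Its lower signal may reflect the partly disrupted 3' region that the labels name, and that was not tested. LEU2, the beta-isopropylmalate dehydrogenase of leucine synthesis, fell 2.26-fold, from 3372 ± 447 to 1477 ± 131 (SD, n = 4 each, limma adjusted p = 5.65e-05). EMC10, on the other side of PST1 from CDC34, rose (log2 fold change 0.82, adjusted p = 6.96e-05), and DBF4, another neighbour, had a log2 fold change of 0.00 (adjusted p = 0.983).

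Of 5437 probe sets tested, 1028 were higher and 1072 lower in CDC34tm. Most changes were small: 203 of the higher and 354 of the lower probe sets changed by at least 1.5-fold, and 43 and 122 by at least 2-fold. The signals of the strains did not overlap for 39.5% of the tested probe sets, where chance gives 2.86%. Centring each array on its median moved the split to 1327 higher and 889 lower, so that 59.9% of the calls were higher in place of 49.0%. Leaving out WT replicates 1 and 4, which stand apart from the other WT arrays in heat shock genes, gave 974 higher and 1138 lower, and leaving out WT replicates 2 and 3 gave 1387 higher and 1224 lower.

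The largest rise was that of PTR2, a transporter of di- and tripeptides, from 439 ± 170 to 3364 ± 687 (SD, n = 4 each, 7.85-fold, limma adjusted p = 8.84e-05). OPT2, an oligopeptide transporter homologue, rose 4.37-fold. PHO89, a sodium-phosphate cotransporter, rose 6.15-fold, and SPL2, which acts in phosphate homeostasis, rose 3.36-fold. PHO89 varied among the WT cultures, so its fold depends on which are included: it read 50.6 and 132 on WT replicates 1 and 4, 340 and 253 on WT replicates 2 and 3, and 836 to 1407 on the CDC34tm arrays. INH1, an inhibitor of the mitochondrial ATP synthase in its hydrolysis mode, rose 3.96-fold with a narrow spread, from 347 ± 46.5 to 1415 ± 57.4 (SD, n = 4 each, limma adjusted p = 2.46e-06), and LSC2, a subunit of succinyl-CoA ligase, rose 3.07-fold. The cell wall genes CWP1 and GSC2 rose 3.46-fold and 2.96-fold. DSE1 rose 3.57-fold, the sulfite pump gene SSU1 3.01-fold, the proteinase inhibitor gene PBI2 2.94-fold and YAR068W 3.02-fold.

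The largest fall was that of HSP30, a stress-induced plasma membrane protein, at 23.8-fold. Its homologue YRO2 fell 12.6-fold, and HSP42, a small heat shock protein, 12.2-fold. All of them, and RTC3 with a 6.19-fold fall, varied widely among the WT cultures. HSP42 read 5770 and 6744 on WT replicates 1 and 4, 978 and 652 on WT replicates 2 and 3, and 144 to 188 on the CDC34tm arrays. Without WT replicates 1 and 4 the falls were 10.9-fold for HSP30, 6.65-fold for YRO2, 4.41-fold for HSP42 and 2.46-fold for RTC3, and all stayed past the threshold. Those arrays were left out for their heat shock values, which narrowed the spread: the SE of HSP42 went from 0.675 to 0.161. Staying past the threshold is therefore weak evidence here. For RTC3 the log2 fold change was -1.30 without WT replicates 1 and 4 and -3.96 without WT replicates 2 and 3. TIS11, which degrades mRNAs in iron deficiency, fell 11.1-fold, and DIP5, a glutamate and aspartate permease, 8.16-fold. SPO19, TDA6 and RRT5 fell 8.05-fold, 7.91-fold and 7.65-fold. SPO19 lay close to background in CDC34tm, at 19.0 ± 4.71 against 276 ± 98.0 in WT (SD, n = 4 each), and its log2 fold change of -3.01 became -1.99 with a pseudocount of 64. PRM7, the transcription factor gene RGM1 and BSC1 fell 5.41-fold, 5.40-fold and 5.36-fold.

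**Figure D1:**
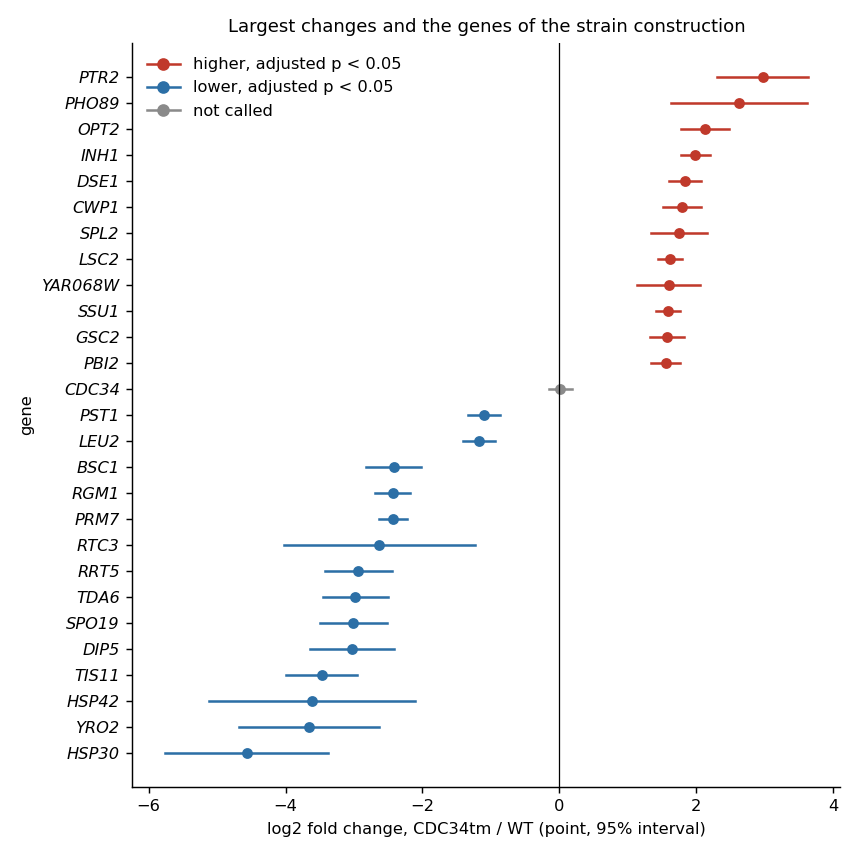
Log2 fold change of CDC34tm over WT (x axis) for the 12 largest rises, the 12 largest falls and the genes of the strain construction (y axis); points are limma estimates, lines their 95% intervals, and colours the call. The estimates run from -4.57 for HSP30 to 2.97 for PTR2, and the interval of CDC34 includes 0.

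Genes of the G1/S transition, which the SBF and MBF factors switch on, were higher. Of 38 measured, 18 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 3.45e-07, and adjusted p = 0.819 with an estimated correlation). The S phase cyclin genes CLB6 and CLB5 rose by 0.97 and 0.90 on the log2 scale, NRM1, a repressor of MBF targets, by 0.88, and the replication protein A subunit gene RFA3 by 0.82. This list depended on which WT cultures were included. Without WT replicates 1 and 4, 35 of 38 rose with a median of 0.68, and without WT replicates 2 and 3, 15 rose and 2 fell with a median of 0.20. Among the genes of the CLB2 cluster, expressed in G2 and M phase, 7 of 18 rose and 0 fell, with a median of 0.24, among them SUR7 (0.68) and MYO1 (0.71). That list was not past the threshold with all arrays (camera adjusted p = 0.0662), but was past it without WT replicate 2 (0.0385) or 3 (0.00664) and after the length correction (0.0326). It too depended on the WT cultures: its median without WT replicates 1 and 4 was 0.02, with 6 up and 6 down (camera adjusted p = 0.566), and without WT replicates 2 and 3 it was 0.48, with 12 up and 0 down. Of the 10 MCM cluster genes, 1 rose and 2 fell (camera adjusted p = 0.816), and of 8 histone genes, 2 rose and 0 fell (camera adjusted p = 0.12), or 0 and 0 adjusted over the list alone.

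Genes for the SCF machinery itself changed in both directions. Of the 11 SCF core and F-box genes, RUB1, which encodes the ubiquitin-like modifier of cullins, rose (0.54), and HRT1, the RING subunit, fell (-0.32, and -0.49 after the length correction), as did the F-box genes SAF1 (-0.48) and DIA2 (-0.20). The other 7, among them CDC53, SKP1 and CDC4, were not called (list camera adjusted p = 0.514, fry adjusted p = 0.0472). Of 16 genes whose proteins are SCF substrates, 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.0662, fry adjusted p = 0.0422). The substrate list was past the camera threshold without WT replicate 3 (0.0114), with the replicate block (0.0487) and after the length correction (0.0401). Its median was 0.08 without WT replicates 1 and 4 (camera adjusted p = 0.295) and 0.37 without WT replicates 2 and 3. SIC1, the inhibitor of S phase cyclin kinase, rose from 1043 ± 122 to 1697 ± 85.8 (SD, n = 4 each, log2 fold change 0.70, limma adjusted p = 3.82e-04). The G1 cyclin gene CLN1 rose by 0.73 and ASH1, a repressor of mating type switching, by 0.46, while STD1, a regulator of glucose transporter genes, fell by 0.25. CLN2, the other G1 cyclin of this pair, had a log2 fold change of 0.28 and was not called (adjusted p = 0.123), but was called without WT replicate 1 (0.39, adjusted p = 0.0338). It was 0.49 without WT replicates 1 and 4 and 0.07 without WT replicates 2 and 3. CDC6, a replication licensing gene, rose by 0.52 and MET4, the activator of sulfur metabolism, by 0.28. Both calls were lost without WT replicate 1 or WT replicate 4, and without CDC34tm replicate 1, 2 or 4, CDC6 also without CDC34tm replicate 3, with adjusted p from 0.0519 to 0.0816. DIA2 lost its call without any single array other than WT replicates 1 and 4, without WT replicates 2 and 3 together (adjusted p = 0.146), after quantile normalization (0.091), centring (0.104) and the length correction (0.0997), and with the replicate block (0.0585). SAF1 lost its call without CDC34tm replicate 2 (0.0523) and after the length correction (0.0515). Without WT replicates 1 and 4 together, CDC6 (0.20), MET4 (0.14) and SAF1 (-0.23) were not called, and without WT replicates 2 and 3 they had larger changes (0.84, 0.41 and -0.73). Outside both SCF lists, CTS1, which encodes a chitinase, rose from 5895 ± 513 to 10610 ± 477 (SD, n = 4 each, log2 fold change 0.85, limma adjusted p = 2.1e-05).

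Nuclear genes for mitochondrial respiration rose together. Of 35 measured, 28 rose and 0 fell (30 and 0 adjusted over the list alone), with a median log2 fold change of 0.46 (camera adjusted p = 6.93e-14, and adjusted p = 0.0537 with an estimated correlation). The cytochrome c oxidase subunit genes COX7 and COX4 rose by 0.88 and 0.83, and the ATP synthase subunit genes ATP14 and ATP16 by 0.62 and 0.57. COX7 went from 2636 ± 64.1 to 4863 ± 253 (SD, n = 4 each, limma adjusted p = 5.6e-06). These genes are short, with a median coding length of 462 bp, and genes of short coding length were on average slightly higher in CDC34tm (Spearman correlation -0.186 of log2 fold change with coding length, across genes, which are not independent replicates). After a correction for coding length 27 of 35 rose, with a median of 0.35.

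**Figure D2:**
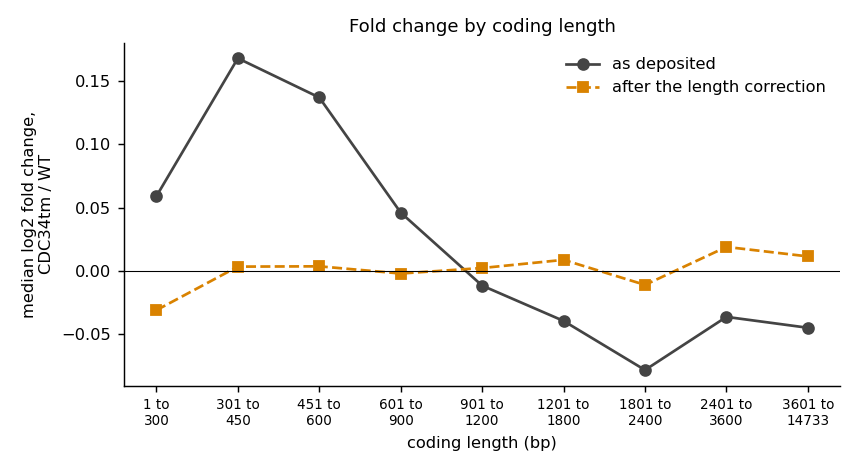
Median log2 fold change of CDC34tm over WT (y axis) for tested probe sets in bins of coding length in bp (x axis), from the deposited signals (circles) and after a correction for coding length (squares). With the deposited signals the bin ending at 450 bp has the highest median, 0.17, and the bin ending at 2400 bp the lowest, -0.08.

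Iron uptake genes, the targets of Aft1, were lower. Of 15 measured, 14 fell and 0 rose, in counts that were the same adjusted over the list alone, with a median of -0.99 (camera adjusted p = 1.92e-08, and adjusted p = 0.536 with an estimated correlation). TIS11 fell from 908 ± 360.1 to 63.9 ± 12.7 (SD, n = 4 each). The siderophore transporter genes ENB1 and ARN1 fell 2.38-fold and 1.90-fold, and the ferric reductase gene FRE3 2.44-fold. FIT1, a cell wall mannoprotein gene of the same regulon, had a log2 fold change of -0.05 and was not called.

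Leucine synthesis genes, which Leu3 activates, were lower as well. Of 14 in the list, 9 fell and 1 rose, again the same adjusted over the list alone, with a median of -0.20 (camera adjusted p = 8.9e-04, and adjusted p = 0.591 with an estimated correlation). After the length correction the median was -0.13 (camera adjusted p = 0.00758). LEU1, which acts one step before LEU2 in the pathway, fell from 6640 ± 571 to 2204 ± 247 (SD, n = 4 each, 3.00-fold). OAC1, a mitochondrial carrier, fell 2.67-fold, and BAT1, the mitochondrial branched-chain aminotransferase, 1.67-fold. The design text lists the leu2 allele for the WT strain alone. The source names give it for every sample as a variable, which does not say that every sample carries it. A difference between the strains at LEU2 may thus bear on these falls, and its share was not tested. Of the other amino acid synthesis genes under Gcn4, 10 of 35 fell and 0 rose (8 and 0 adjusted over the list alone), with a median of -0.07, and THR1 (-0.43), ARO1 (-0.29), TRP4 (-0.29) and LYS1 (-0.26) were among them. The list was barely past the threshold (camera adjusted p = 0.0486, adjusted p = 0.821 with an estimated correlation, and fry adjusted p = 0.109). It was lost without CDC34tm replicate 1 or 3 or WT replicate 1, 2 or 3 (adjusted p from 0.0503 to 0.0951), without the trend in eBayes (0.0786), after centring (0.0918) and after the length correction (0.107), and its median was -0.10 without WT replicate 4. Of the 35 genes, 18 fell without WT replicates 1 and 4 with a median of -0.16 (camera adjusted p = 0.00343), and without WT replicates 2 and 3, 5 fell with a median of -0.06 (0.348).

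Ergosterol synthesis genes fell in part. Of 23, 6 fell and 1 rose (4 and 1 adjusted over the list alone), with a median of -0.10 (camera adjusted p = 0.0262, and adjusted p = 0.819 with an estimated correlation). ERG28, a scaffold of the sterol demethylation complex, fell by 1.03 on the log2 scale, HMG1, an HMG-CoA reductase, by 0.55, ERG3 by 0.43 and ERG26 by 0.21. The call was lost without WT replicate 1 (adjusted p = 0.0919), without WT replicates 1 and 4 (0.295), after centring (0.0611) and after the length correction (0.0608). It was kept without WT replicates 2 and 3 (median -0.17, 0.00294). ERG26 lost its own call without CDC34tm replicate 1 (0.0554) or 3 (0.0523), after centring (0.0781) and without WT replicates 1 and 4 (0.0912).

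Heat shock genes were lower in CDC34tm, against WT cultures that differed among themselves. The heat shock list, added after the data were seen, had 15 of 22 genes lower and 1 higher, with a median of -0.52. Over the 3 added lists alone, the adjusted p was 6.76e-05 by camera, 0.779 by camera with an estimated correlation, and 0.0613 by fry. Its median log2 signal was 12.5 and 12.7 on WT replicates 1 and 4, 11.5 and 11.4 on WT replicates 2 and 3, and 10.9 to 11.1 on the CDC34tm arrays. HSP82 (-2.31), HSP78 (-2.02), BTN2 (-2.15) and SIS1 (-1.30), chaperone and sorting factor genes, fell, whereas the small heat shock gene HSP26 rose (0.71). The general stress genes under Msn2 and Msn4 were mixed: 14 of 31 fell and 2 rose, with the same counts adjusted over the list alone and a median of -0.37 (camera adjusted p = 0.0529). HSP12, a membrane chaperone, went the other way without passing the test (log2 fold change 1.58, adjusted p = 0.0963). This list was past the threshold without WT replicate 2 (0.00564), WT replicate 3 (0.00563) or CDC34tm replicate 4 (0.0438), and after quantile normalization (0.0466), centring (0.0166), the replicate block (0.0325) or the length correction (0.0401). Its members gave 6 up and 13 down without WT replicates 1 and 4, with a median of -0.13 (camera adjusted p = 0.566), and without WT replicates 2 and 3 the median was -1.05.

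**Figure D3:**
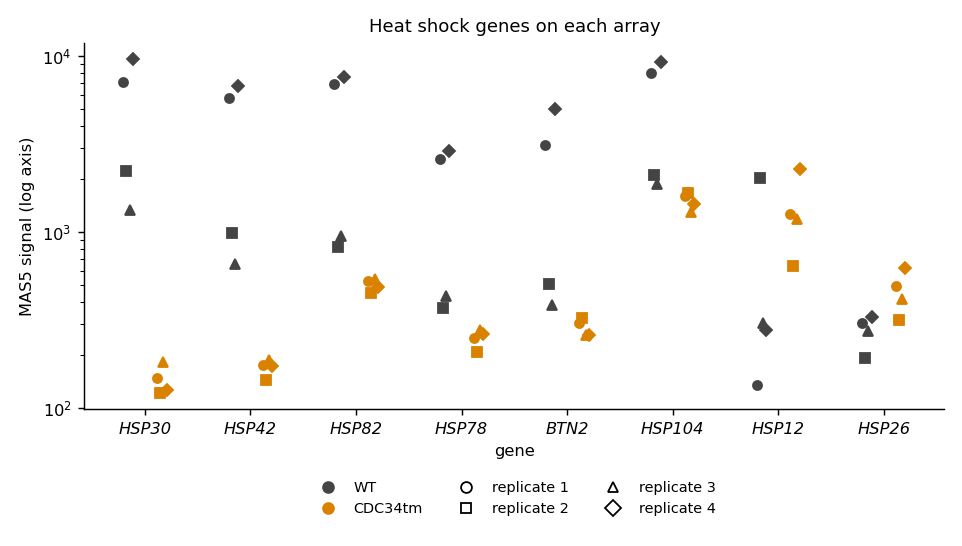
MAS5 signal (log axis) of 8 heat shock genes (x axis) on each of the 8 arrays, with WT in grey, CDC34tm in orange and a symbol per replicate number. For HSP42 the WT arrays range from 652 to 6744 and the CDC34tm arrays from 144 to 188.

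The proteasome genes moved with the same WT cultures. Of 34, 14 fell and 0 rose (15 and 0 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 3.06e-04, adjusted p = 0.821 with an estimated correlation, and fry adjusted p = 0.13). RPN4, the activator of proteasome genes, fell by 0.62 on the log2 scale, and the 19S subunit genes RPN2, RPT3 and RPT1 by 0.45, 0.41 and 0.36. Without WT replicates 1 and 4 the list lost its call (median -0.05, camera adjusted p = 0.455), as did RPT1 (-0.21, adjusted p = 0.0551). RPN2 (-0.27) and RPT3 (-0.21) kept theirs with smaller falls, as did RPN4 (-0.48, adjusted p = 5.01e-04). Without WT replicates 2 and 3 the list median was -0.34.

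Cell wall and nutrient genes changed in both directions. Of 19 cell wall integrity genes, 5 rose and 7 fell (6 and 9 adjusted over the list alone, camera adjusted p = 0.903): CWP1, GSC2 and PIR1 (0.50) rose, while PST1, the transcription factor gene RLM1 (-0.96) and the kinase gene SLT2 (-0.64) fell. For PST1 the fall may reflect its partly disrupted 3' region. Of 16 genes for glucose transport and its regulators, 8 fell and 2 rose (9 and 2 adjusted over the list alone, camera adjusted p = 0.0662, fry adjusted p = 0.0343), and camera called the list after quantile normalization (0.0466). The repressor genes MIG3 (-2.03) and MIG2 (-1.39) and the low-affinity transporter gene HXT1 (-0.91) fell, and the high-affinity transporter gene HXT7 rose (1.12). Of 15 phosphate genes, 4 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.0988), with PHO89, SPL2 and PHM6 (1.18) up and PHM8 (-2.26) down. Of 29 sulfur amino acid genes, 9 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.065). This list was past the threshold without WT replicate 1 (2.3e-04) or 4 (0.0383), with the replicate block (0.0341) and after the length correction (0.0249). Of the 29, 19 rose and 1 fell without WT replicates 1 and 4, with a median of 0.23, and without WT replicates 2 and 3, 6 rose and 3 fell with a median of 0.02. Of 19 nitrogen catabolite genes, 3 rose and 4 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.816).

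Of 127 cytosolic ribosomal protein genes, 4 rose and 0 fell, none of them adjusted over the list alone (median 0.01, camera adjusted p = 0.587). Ribosome biogenesis genes had 5 of 53 higher and 0 lower, with 0 and 0 adjusted over the list alone (camera adjusted p = 0.0662), and were past the threshold without WT replicate 2 (0.00376) or 3 (0.00664), with the replicate block (0.0341) and after the length correction (0.00564). Their direction depended on the WT cultures: without WT replicates 1 and 4 the median was -0.07, with 1 up and 7 down (camera adjusted p = 0.326), and without WT replicates 2 and 3 it was 0.25, with 34 up and 0 down. Glycolytic genes had 5 of 15 lower and 0 higher, the same adjusted over the list alone (camera adjusted p = 0.0662), and were past it without CDC34tm replicate 2 (0.0131) or WT replicate 4 (0.0383) and after quantile normalization (0.02), but not without WT replicates 1 and 4 (0.23). Of 12 DNA damage genes, 2 rose and 3 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.903). The mating type markers differed little: 0 of 7 a-specific genes were called, 0 also adjusted over the list alone (camera adjusted p = 0.903), and 1 of 4 alpha-specific genes fell, MF(ALPHA)2 by 0.32, the same adjusted over the list alone (camera adjusted p = 0.459). Of 22 pheromone response genes, 2 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.459). Their median log2 signal stood apart on WT replicate 3, at 11.0 against 9.78 to 10.2 on the other 7 arrays. The pheromone list was past the threshold without WT replicates 1 and 4 (median -0.46, adjusted p = 0.00728, 0 up and 8 down). Without WT replicates 2 and 3 its direction was the opposite (median 0.23, 9 up and 3 down).

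**Figure D4:**
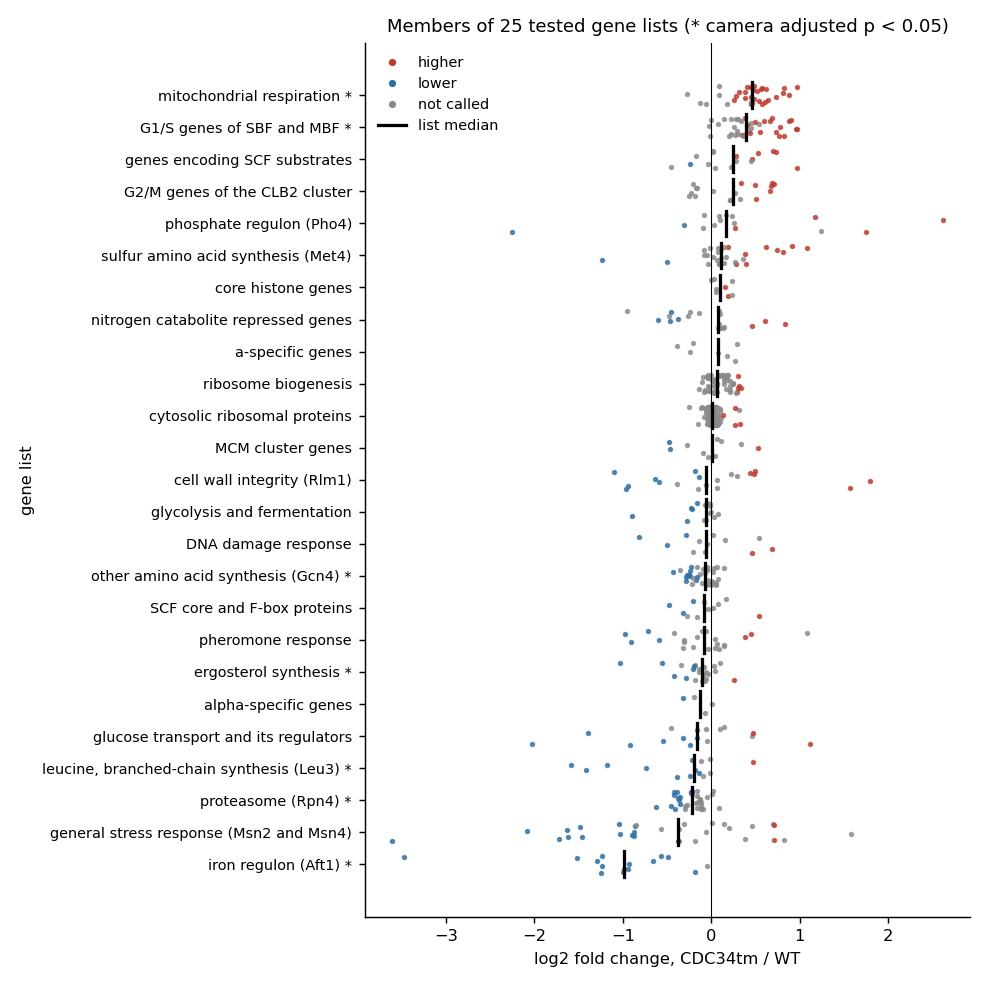
Log2 fold change of CDC34tm over WT (x axis) of each member of 25 of the tested gene lists (y axis, ordered by median); dots are genes coloured by call, bars are list medians, and asterisks mark lists past the camera threshold. Medians run from -0.99 for the iron regulon to 0.46 for mitochondrial respiration.

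By camera with its preset correlation, 8 of the 26 lists were past the threshold, 3 higher and 5 lower. With an estimated correlation camera called 0, with 2 lists under an unadjusted p of 0.05 and a smallest adjusted p of 0.0537, and fry called 9. Fry called the SCF core and F-box, SCF substrate and glucose transport lists, which camera had not, and did not call the proteasome and Gcn4 lists. Of the 35 ways to split the 8 arrays into 4 and 4, 29 gave at least 8 lists past the preset threshold. The number of list calls is therefore weak evidence. No other split gave a call of a single gene, but all of them mix the strains, which widens the spread within groups. Among array quality measures, the 3' to 5' ratio of the SPT15 control probe sets was 1.99 ± 0.156 in CDC34tm and 2.38 ± 0.107 in WT (SD, n = 4 each, exact permutation p = 0.0286, the smallest possible, and 0.1 adjusted over 7 measures). The 7 include the median of the heat shock list, which is not a quality measure. It had the same exact permutation p, 0.0286, which lowers the adjusted value for SPT15. The same ratio for ACT1 was 1.29 ± 0.0267 and 1.32 ± 0.0564 (exact permutation p = 0.457).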

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

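The splits of the arrays were planned; the tests of both patterns below were chosen after the results had been seen.

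Of 186 sets of 4 values, one per strain for each named gene and tested list, 10 held an array far from the other 3, where chance gives about 9.3, so the number of such sets is no more than chance. The gap to the nearest array, as a share of the range, was 0.831 for DIP5, 0.837 for SCW11 and 0.917 for STD1, each highest on CDC34tm replicate 1. It was 0.945 for BSC1, highest on WT replicate 3, 0.891 for DSE2, lowest on WT replicate 1, and 0.869 for CLB5, lowest on CDC34tm replicate 2. Among list medians, it was 0.834 for the MCM cluster and 0.964 for general stress genes, both lowest on CDC34tm replicate 2. It was 0.838 for Gcn4 genes and 0.858 for glycolysis, both highest on WT replicate 1.

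Outside the main measurement, 338 probe sets without a name in the table used lay above background on at least 4 arrays, of which 42 were higher and 29 lower in CDC34tm. Of 47 reporter control probe sets, 9 lay above the stricter background. The one with the largest change read 2267 to 5810 on the CDC34tm arrays and 5594 to 6899 on the WT arrays.

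The 2100 called probe sets could be set against the 35 ways of splitting the 8 arrays into 4 and 4. Only 1 of them, the real one, gave as many, and the highest of the others gave 0. That share, 2.86%, is the smallest that 35 splits can give. Every other split mixes the strains, so the strain difference widens the spread within its groups and lowers its calls. The splits argue against chance for the count at that limit only, and cannot tell strain from an unrecorded batch of cultures. For gene lists past the camera threshold chance cannot be excluded: the real split gave 8, 29 of the 35 splits gave at least as many, and the highest other gave 15. List by list, the median of 6 of the 8 called lists was the largest of all 35 splits in size. The same held for 9 of all 26 lists, uncalled ones among them, so it does not mark the called lists alone. For the proteasome list the margin was narrow, 0.215 against 0.213 in the highest other split. The exceptions among the 8 were the G1/S genes and the Gcn4 genes, for which 2 and 5 splits, the real one included, gave a median as large.

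Heat shock genes were lower in CDC34tm, and 2 WT cultures carried the highest values. Those cultures did not carry the whole measured difference: without WT replicates 1 and 4 the median of the 22 genes was still -0.365, and both other WT arrays lay above every CDC34tm array. The smallest permutation p that 2 against 4 arrays can give is 0.067, and the list was added after the data were seen. This separation of list medians by itself therefore does not exclude chance. A general stress state shared with Msn2 and Msn4 targets stays open. The 26 genes of that list outside the heat shock list had a median of -0.0474 without the same arrays, but an SD over members of 0.753. Some difference in growth or handling of the WT cultures could account for the size of the fall, but the labels give no batch or day. An effect of the strain stays open and was not tested.

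Respiration genes were higher in CDC34tm. The tables argue against a trend with coding length as the whole cause, since the median was 0.354 after the correction and the list stayed past the threshold at the preset correlation (camera adjusted p = 2.09e-11). With an estimated correlation the list was not called before any correction (adjusted p = 0.0537). They also argue against a like rise of all genes for mitochondrial proteins, since mitochondrial ribosomal protein genes had a median of 0.129, below 0.456 by more than their SD of 0.266. A general release from glucose repression cannot be told apart. Of 10 tricarboxylic acid cycle genes 2 rose and 1 fell, with a median of -0.0736 but an SD over members of 0.605, from IDH1 (-0.63) to LSC2 (1.62). By mean per array, respiration genes rose more than mitochondrial ribosomal genes by 0.34 and more than tricarboxylic acid cycle genes by 0.39. The exact permutation p was 0.0286 for each, the smallest possible. It covers the spread between arrays and not that among the genes of a list, so it leaves such a release open. An effect of the strain stays open beside such a release. Neither that nor the share of the NatR marker, PST1 and the leu2 allele, which the labels name as variables, was tested.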

How the results depend on the processing

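The settings chosen in advance kept the direction and the side of the threshold for 58 of 64 named genes beside CDC34, PST1 and LEU2, and those added after seeing the data for 57. Of 26 lists, 10 kept their side of the threshold under every setting and test chosen in advance, 17 with the changes of test left aside, and 16 under the added settings. Some lists without a call turned in sign. PST1 and LEU2 stayed lower and past the threshold, and CDC34 stayed short of it, under every setting run on them. The count of lists moved from 8 to 0 when camera estimated the correlation, which its construction explains, as the test allows for genes that vary together. After the length correction the median of the cytosolic ribosomal protein genes turned from 0.01 to -0.0327 (camera adjusted p = 0.0401), and the cause was not tested. The lengths used for these genes had a median of 771 bp and may hold more than coding sequence. The turn in sign may thus come from the lengths used, and nothing is concluded from it.

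Across the settings that left out 1 array, 756 to 1055 probe sets were higher and 833 to 1064 lower, 7 to 11 lists were past the threshold, and log2 fold changes were -0.03 to 0.06 for CDC34, -1.15 to -1.02 for PST1 and -1.28 to -1.13 for LEU2. Quantile normalization gave 1182 higher and 978 lower. The replicate numbers showed no clear pairing of the cultures: deviations of arrays with the same number correlated at 0.0381, 0.227, -0.0754 and 0.0629, and 3 of 8 arrays correlated best with their own number. Low correlations cannot exclude that cultures were handled in pairs, and the labels do not say whether they were. With the replicate number as a block, 975 were higher and 1018 lower, and 12 lists passed. Dim genes are limited by the background: the filter left out 61 probe sets, and without it 1025 were higher and 1066 lower.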

Other observations

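The tests of neighbouring genes below were chosen after the pattern had been seen.

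Several falls lay side by side at the right end of chromosome XV. From GDH1 to YOR389W, 15 neighbouring measured genes had a median log2 fold change of -0.526, with 10 lower and 1 higher in CDC34tm. Among them were GDH1 (-0.39), a glutamate dehydrogenase, ATF1 (-0.35), an alcohol acetyltransferase, AMF1 (-2.25), an ammonium facilitator, RDR1 (-0.56), a repressor of drug resistance genes, and the iron genes FRE3 (-1.29), FIT2 (-0.99) and FIT3 (-1.23). YOR387C rose (0.46). Among the 32 chromosome ends, taken as the last 20 measured genes, this end had the lowest median, -0.42, the next lowest being -0.17 and the highest 0.16. The run had been picked for the largest median in size, and its start lies 18 measured genes from the end. The end thus holds the whole run, and its rank largely follows from that choice. Medians of the 16 whole chromosomes ran from -0.04 to 0.05, far from the log2 shift of 1 that an extra copy in a haploid would give.

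A placement of these genes unrelated to their change is argued against, since shuffling the order of genes gave a run with as large a median at a permutation p of 0.015 over 1000 shuffles. The shuffles treat neighbours as independent, which genes of one regulon are not. Of the 15 genes, 3 belong to the iron list, and the share of iron regulation in the run was not tested. A sequence or chromatin difference between the strains at this end is a candidate explanation that expression values cannot test.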
